A study of Mus musculus with 2 samples.

How the data were processed

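MEF2A ChIP-seq peak lists from 2 biological replicates of the mouse MEL cell line were analysed. The labels name 1 group and give the replicate numbers. They do not say how far apart the cultures were grown. All lists are on mm10, per the labels. The aligner, the peak caller and their versions are not given in the sources used here, and the control library was not analysed here.

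Per the deposited file listing, the lists came from 2 processing runs. The relaxed lists, the optimal list and the conservative list of 1868 peaks came from one run. The ranked lists, the replicates' own thresholded lists and the conservative list of 1874 peaks came from the other. Comparisons of these with the relaxed or optimal lists, including the replicate signals at conservative peaks, therefore cross the runs. Each replicate, and the reads of both pooled, had a relaxed list of peaks and background made against a control, with at most 300000 entries (114316 for replicate 1, 300000 for replicate 2). Such lists are the input to the irreproducible discovery rate (IDR) procedure, which keeps peaks whose ranks agree between lists. The signal of each peak is the peak caller's own value as deposited, on a scale that is not stated, and it was used to rank and describe peaks within a list. The score of each peak in the deposited lists is the IDR score. The ranked lists also give the −log10 of the global IDR, per the deposited file listing. In those lists a score of 540 or more went with a global IDR of up to about 5%, and a few peaks past that score were missing from the thresholded lists (1877 against 1874 for the conservative list, 508 against 483 for replicate 1). The threshold lists of the single replicates were made within each replicate, and the conservative list between the replicates. Of 2 conservative lists, of 1874 and 1868 peaks, the one with more peaks was used, and 94.3% of its peaks overlapped the other.

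The deposited coordinates were compared with the GRCm38 reference, the assembly behind mm10, and no peak ran past the end of a chromosome. Gene models were the GENCODE vM21 basic set. Coordinates are 1-based. Only peaks on the assembled chromosomes 1 to 19, X and Y entered the comparisons.

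Overlap needed at least 1 bp, and was compared with peaks placed at random on the same chromosomes, 100 times for thresholded lists and 10 times for relaxed lists, fewer than the 100 intended, because those lists are long. A replicate's signal at a conservative peak was the highest value of an overlapping entry in its relaxed list. Positions were classed by the summit, first as promoter (up to 1 kb from any TSS) and then by gene part, and compared with 200000 random assembled positions by exact binomial tests.

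Motifs were IUPAC consensus matches on either strand in the 101 bp window at the summit (50 bp on either side). The background was a window of the same size whose near edge lay 1000 bp upstream of the summit on the reference strand. Peak and flank were compared by an exact McNemar test, with Benjamini-Hochberg adjustment over 23 motifs. Peak classes were compared by Fisher's exact test, two-sided, with Newcombe intervals of the difference. Shares have Wilson 95% intervals unless called exact, and intervals cover counting error only. For a count of 0 the limit is 3 counts of the total. A gene counted as near a peak when a summit lay within 5 kb of any of its TSSs, so genes with many TSSs had more chances. The 17 gene lists had 417 members, of which Hbb-b1 and Ahsp matched no protein-coding gene of the annotation. Symbols were also matched through synonyms, and Mfsd7b and Flvcr1, the same gene, counted once. The background was the other protein-coding genes of 21911. Because peaks are not replicates of the experiment, p-values over peaks or genes speak of these lists.

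The named items followed a rule set before the data were examined, as were the motif panel, the gene lists and the main tests: the 25 conservative peaks of highest signal value with the nearest protein-coding gene, up to 6 members per list by signal value with a summit within 5 kb, and the MEF2 family, Gata1, Tal1, Klf1 and adult globin genes whether bound or not. Hbb-bs and Hbb-bt stand for Hbb-b1. All 9 bound immediate early genes are named, 3 more than the rule allows, so that the count can be read. Other genes named in the closing section, Rbm20 and the Hdac6 promoter were chosen after their values were seen.

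Alternatives were other overlap rules, peak lists, windows, backgrounds, promoter widths and gene distances, the stronger 937 peaks, and each replicate's own list as the result without the other. On simulated data, MEF2 motifs planted in 2% of 1874 random windows were recovered in 80% of 20 draws, and GATA motifs planted in 20% were recovered in 100%. With nothing planted, 2 of 460 motif tests were called. With motifs planted, 4 of 320 tests of other motifs were called. A list of genes bound at an added 25% was recovered in 94% of 100 draws over 21911 genes, and 1 of 1700 list tests was called with nothing planted. Overlap counts were equal to those of bedtools in 6 of 6 cases. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1, with a random seed of 7.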

Results

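Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against MEF2A was carried out in MEL cells, a mouse erythroleukemia line arrested at an early stage of red cell development. MEF2A is a MADS-box transcription factor best known from muscle and neurons. The series held 1 group of 2 biological replicates, so the comparisons were between the replicates, between peaks and their surroundings, and between classes of peaks. The analysed files were peak lists on the mm10 genome. They gave no read counts, and the sequencing depth of each replicate was therefore unknown. Replicate 1 had 483 peaks past the authors' reproducibility threshold and replicate 2 had 3598. The conservative list, made from both replicates, had 1874 peaks, and the optimal list had 5014.

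The first comparison asked how far the replicates found the same sites. Of the replicate 1 peaks, 431 of 483 (89.2%, exact 95% interval 86.1 to 91.9) overlapped a replicate 2 peak by at least 1 bp. In the other direction, 436 of 3598 replicate 2 peaks (12.1%, 11.1 to 13.2) overlapped a replicate 1 peak. Randomly placed peaks overlapped in 0.0683% and 0.0108% of cases (means of 100 placements). The strongest shared sites included Ywhah, which encodes a 14-3-3 adaptor protein, and Hdac5, a class IIa histone deacetylase that binds MEF2 factors. At the Ywhah promoter the deposited signal value was 117 in replicate 1 and 169 in replicate 2. At the Hdac5 promoter it was 110 and 146. The list lengths bear on both shares: with replicate 2 trimmed to its strongest 483 peaks, 62.1% of replicate 1 peaks and 61.9% of replicate 2 peaks were shared.

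Across the 1851 conservative peaks with a value in both relaxed lists, Spearman's rho of the replicates' signal values was 0.525 (95% interval by Fisher's z, 0.489 to 0.559). The conservative list keeps peaks whose ranks match between the replicates, so rho describes peaks selected on this very quantity and not MEF2A sites in general. Peaks are also not independent replicates. The median signal value at these peaks was 8.16 in replicate 1 and 26.5 in replicate 2, with a median ratio of 3.08. The scale of the deposited signal values is not stated, so this ratio cannot be read as a difference in occupancy.

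**Figure D1:**
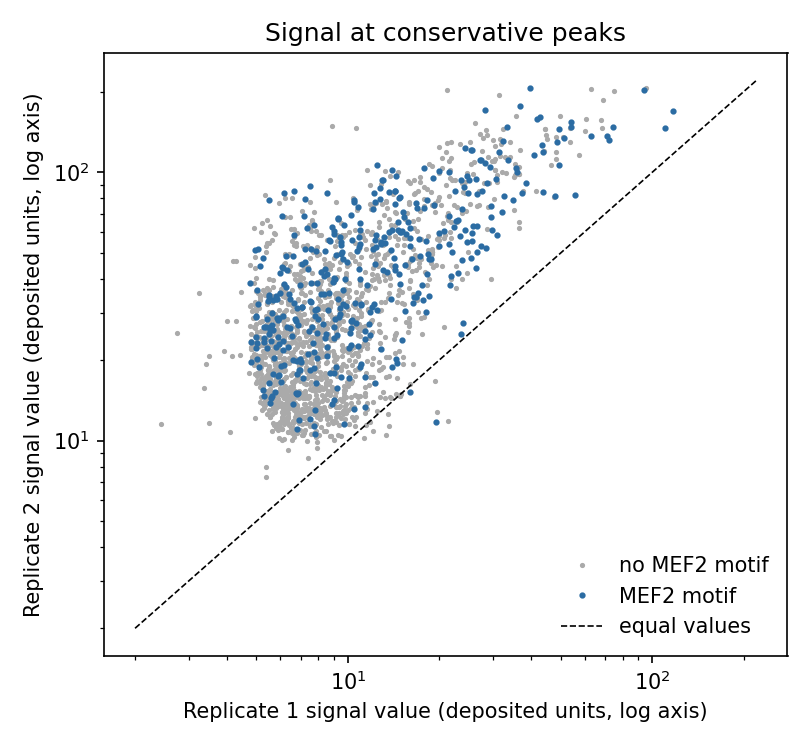
Deposited signal values of replicate 1 (x, log axis) and replicate 2 (y, log axis) at the 1851 conservative peaks present in both relaxed lists, 1 point per peak, with blue points for peaks that hold the MEF2 consensus. Nearly all points lie above the dashed line of equal values, and the median ratio of replicate 2 to replicate 1 is 3.08.

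MEF2A peaks lay in introns and near transcription start sites (TSSs) more often than random positions did. Promoters, meaning summits up to 1 kb from an annotated TSS, held 353 of 1874 conservative summits (18.8%, Wilson 95% interval 17.1 to 20.7) against 4.42% of random positions. Introns held 881 (47.0%, 44.8 to 49.3) against 41.4%, and intergenic sequence held 589 (31.4%, 29.4 to 33.6) against 51.2%. Exact two-sided binomial tests gave p = 1.4e-116 for promoters, 8.2e-07 for introns and 2.7e-67 for intergenic sequence. By the same exact test, coding exons held 13 summits (0.694% against 1.17%, p = 0.0659) and 3' UTRs held 28 (1.49% against 1.17%, p = 0.197), neither past the threshold. The median distance from a summit to the nearest TSS was 8328 bp, against 20177 bp for random positions. Both replicates' own lists had a promoter share above random, at 17.0% in replicate 1 and 20.5% in replicate 2. The excess in introns fell to 1.29 points (exact binomial p = 0.244) when promoters were widened to 5 kb.

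The 25 strongest conservative peaks lay nearest to 24 protein-coding genes, and all 25 were in both replicates' own lists. The strongest, with a signal value of 296, was in an intron of Rbm20 at chromosome 19:53802027-53802292, and the nearest protein-coding TSS was that of Pdcd4, a translation inhibitor gene, 90077 bp away. It held a GATA motif (WGATAR) and no MEF2 consensus (YTAWWWWTAR). Hdac5 had 2 peaks among the 25: one in its intron at chromosome 11:102218840-102219131 (signal value 295), with the MEF2 sequence CTATAAATAG at 102218983-102218992, and one at its promoter at chromosome 11:102230059-102230328 (264), with CTAAAAATAG at 102230183-102230192, 24 bp from the TSS by its summit. The Ywhah promoter peak at chromosome 5:33018570-33018817 had a signal value of 282 and held CTATTTATAG at 33018706-33018715. Tmod1, which encodes the actin filament capping protein tropomodulin of the red cell membrane skeleton, had an intronic peak at chromosome 4:46040747-46040974, 1923 bp from its TSS, with a signal value of 209 and the sequence CTAAAAATAG at 46040831-46040840. A peak 16793 bp from Slc38a2, an amino acid transporter gene, held TTAAAAATAG at 96716475-96716484 on chromosome 15 and had a signal value of 238.

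Other genes nearest to these peaks were Lims1 (276), Ung (262), which encodes uracil-DNA glycosylase, Rlbp1 (260), Otulin (244), Anxa3 (229), Mxi1 (228), which encodes a MAX partner that opposes MYC, Ercc1 (227), Pbx1 (214), Artn and Oxsr1 (212 each), and Rubcn (211), each with its peak's signal value. Egln3, a prolyl hydroxylase of the hypoxia pathway, and Wee1, a kinase that holds back mitosis, had values of 208 each, at distances of 40948 and 42230 bp. Rnf10 (207), Pigl (206), Slc13a4 (205), Alpk1 (204), Olfml2b (202) and Mical1 (201) completed the 25. Of the 25 peaks, 13 held the MEF2 consensus and 21 held a GATA motif, with 9 holding both, 12 GATA alone and 4 MEF2 alone. Distances to these genes reached 143142 bp for Pbx1, and a nearest gene is a position, not a measured target.

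The GATA motif and the MEF2 consensus exceeded the flanks by the most points, at 41.9 and 19.5, although rarer motifs had higher ratios. Within 50 bp of the summit, 400 of 1874 conservative peaks (21.3%, Wilson 95% interval 19.5 to 23.3) held YTAWWWWTAR, against 1.87% of windows 1 kb upstream, an 11.4-fold difference. The palindromic core CTAWWWWTAG was in 11.5% against 0.160%. GATA motifs, which bind the erythroid regulator GATA1 and its relatives, were in 1130 peaks (60.3%, 58.1 to 62.5) against 18.4%. A spaced E-box and GATA element bound by TAL1 and GATA1 together was in 4.96% of peaks against 0.427% at a spacing of 8 bp. The MYB motif was in 15.2% against 9.07%, the RUNX motif in 13.7% against 9.45%, and the ETS motif in 1.33% against 0.107%.

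Across the panel of 23 motifs, 15 were above the upstream flank and 0 below it by exact McNemar tests with Benjamini-Hochberg adjustment. The adjusted p was 4.5e-83 for MEF2, 8.8e-145 for GATA, 1.0e-18 for the E-box and GATA element, 5.9e-08 for MYB, 1.2e-04 for RUNX and 1.9e-05 for ETS. The motifs of NF-Y (2.93% against 2.72%, adjusted p = 0.844, exact) and TEAD (2.35% against 2.77%, adjusted p = 0.546, exact) did not pass, and the CG-rich palindrome was in 0 of 1874 peaks, which allows a share of up to 0.160%. Equal numbers of 483 peaks per replicate were compared: all of replicate 1's list and the strongest of replicate 2's. The MEF2 share was 30.8% in replicate 1 and 35.6% in replicate 2 (33.2% ± 3.37, SD, n = 2). The GATA share was 61.5% and 71.0% (66.3% ± 6.73, SD, n = 2). This spread therefore also holds a difference in how far down each list the peaks reached. Both excesses over the flanks, which held 2.07% for MEF2 in both replicates and 19.0% and 20.3% for GATA, were larger than this spread. The count of motifs above the flank was 7 in replicate 1's own list, and 7 in the 937 strongest conservative peaks. RUNX (adjusted p = 0.579, exact McNemar test) and ETS (0.0898) did not pass in replicate 1's own list, and both passed in replicate 2's (9.1e-11 and 3.3e-06). In the 937 strongest peaks, ETS did not pass (0.147) and RUNX did (0.00500). The downstream flanks of the conservative peaks held ETS in 0.374%.

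**Figure D2:**
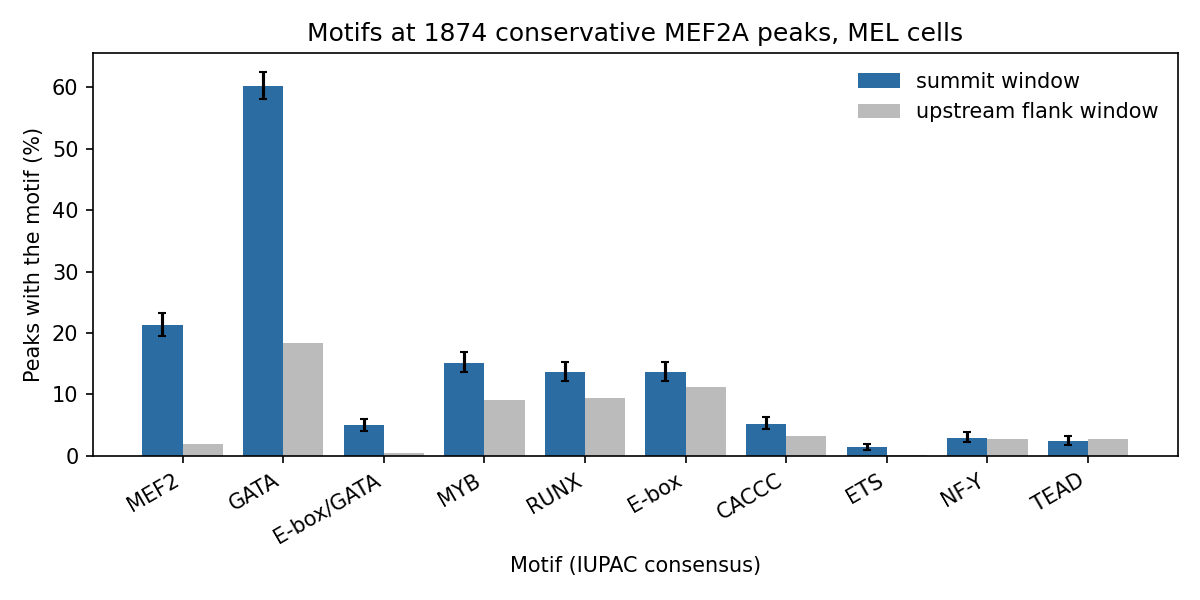
Share of the 1874 conservative peaks (y, percent) with each of 10 motifs (x) in the 101 bp window at the summit (blue, with Wilson 95% intervals) and in the window 1 kb upstream (grey). The MEF2 consensus is in 21.3% of summit windows against 1.87%, and the GATA motif in 60.3% against 18.4%.

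Promoter and distal peaks held different motifs, and GATA differed by the most percentage points, although rarer motifs differed by higher ratios. GATA motifs were in 1030 of 1521 distal peaks (67.7%) and in 100 of 353 promoter peaks (28.3%), a difference of 39.4 points (95% interval 33.9 to 44.4; Fisher's exact test, two-sided, p = 9.9e-42). RUNX (16.0% against 3.68%), the E-box of TAL1 and other bHLH factors (15.1% against 7.37%) and MYB (16.3% against 10.2%) were also more frequent in distal peaks. So was the E-box and GATA element with a 7 bp spacer (3.68% against 0.567%). With the 8 bp spacer it was in 5.46% against 2.83% and did not pass (adjusted p = 0.0675, Fisher's exact test). Promoter peaks more often held CACCC boxes (13.3% against 3.35%), NF-Y motifs (8.22% against 1.71%), GC boxes (7.37% against 0.526%), MYC-type E-boxes (5.67% against 1.91%) and ETS motifs (5.38% against 0.394%). Over the 23 motifs, 5 were more frequent in distal and 7 in promoter peaks at an adjusted p below 0.05 (Fisher's exact test with Benjamini-Hochberg adjustment). These shares were not set against flanks or matched for GC content. Median GC content was 48.0% in the stronger and 62.4% in the weaker promoter peaks, against 42.6% and 44.6% in the distal ones. The differences were thus not shown to be particular to bound sequence.

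The MEF2 consensus was in 337 of 1521 distal peaks (22.2%) and in 63 of 353 promoter peaks (17.8%), a difference of 4.31 points (−0.470 to 8.54) that did not pass Fisher's exact test (p = 0.0834). The direction turned with peak strength. Among the 937 strongest peaks, the consensus was in 48 of 120 promoter peaks (40.0%, Wilson 95% interval 31.7 to 48.9), including those of Ywhah, Hdac5, Mef2a, Klf6 and Nr4a1, and in 248 of 817 distal peaks (30.4%, 27.3 to 33.6; Fisher's exact p = 0.0359). Among the 937 weakest, examined after the data were seen, it was in 15 of 233 promoter peaks (6.44%, 3.94 to 10.3) and in 89 of 704 distal peaks (12.6%, 10.4 to 15.3; Fisher's exact p = 0.00799). These p-values were not adjusted for multiple tests, and the direction also differed between the lists of replicate 1 (−11.3 points, p = 0.0493, Fisher's exact test) and replicate 2 (8.34 points, p = 1.0e-08). The distal excess also passed in the optimal list (7.95 points, p = 1.6e-13, Fisher's exact test), within 100 bp of the summit (p = 0.0191) and with promoters up to 500 bp (p = 0.00837) or 5 kb (p = 0.0329), and was 0.811 points within 25 bp (p = 0.719).

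**Figure D3:**
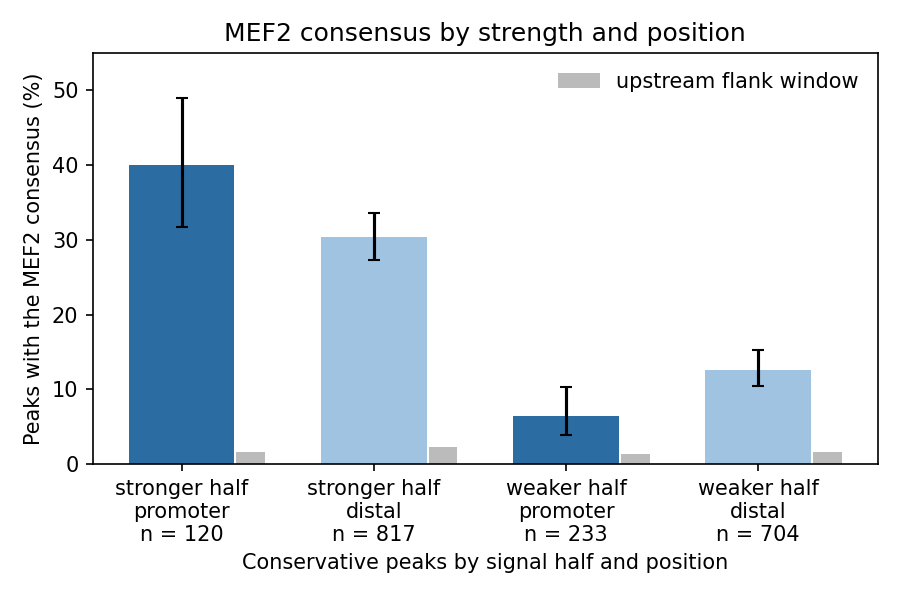
Share of conservative peaks with the MEF2 consensus (y, percent; bars with Wilson 95% intervals) among the stronger and weaker peaks, 937 each, at promoters (dark) and elsewhere (light), with the upstream flank beside each (narrow grey). Promoter peaks hold it in 40.0% of the stronger and 6.44% of the weaker peaks, distal peaks in 30.4% and 12.6%.

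Strong peaks held the MEF2 consensus far more often than weak ones. It was in 179 of the 468 peaks of highest signal value (38.2%) and in 37 of the 468 of lowest (7.91%), a difference of 30.3 points (95% interval 25.2 to 35.3; Fisher's exact test, two-sided, p = 1.3e-29). GATA motifs went from 68.6% to 49.1%, a difference of 19.4 points (13.2 to 25.5; adjusted p = 1.5e-08 over the 23 motifs, Fisher's exact test). RUNX motifs were in 13.5% of the strong and 13.7% of the weak peaks, a difference of −0.214 points (−4.62 to 4.20). The share of promoter peaks was 10.9% in the strongest of the 4 classes by signal value and 31.6% in the weakest.

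**Figure D4:**
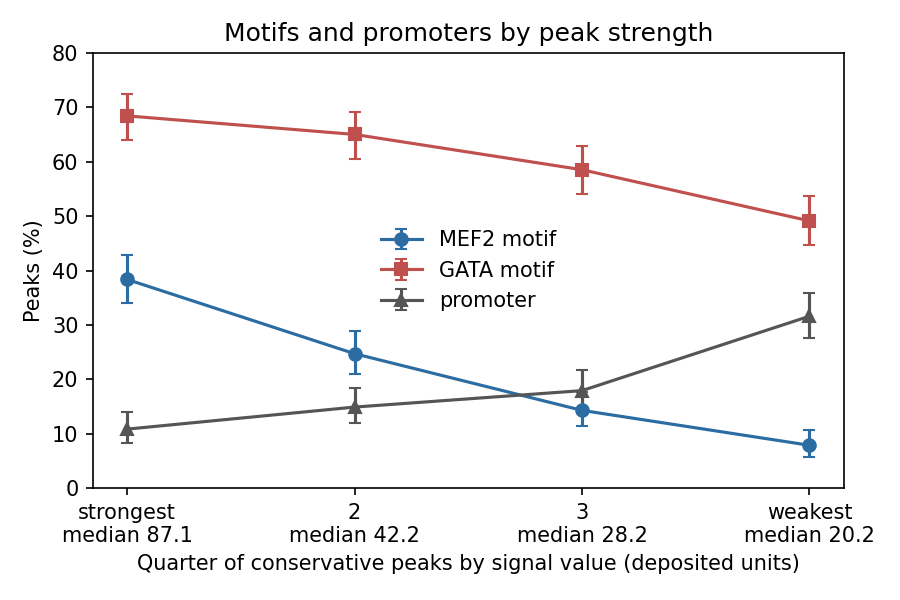
Share of conservative peaks (y, percent, with Wilson 95% intervals) with the MEF2 consensus, with a GATA motif, and at a promoter, in 4 classes by signal value (x, strongest to weakest, with the median signal value of each). The MEF2 share is 38.4% in the strongest class and 7.91% in the weakest, while the promoter share is 10.9% and 31.6%.

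Peaks found in both replicates carried the MEF2 consensus more often than peaks found in one. Of replicate 2 peaks that overlapped a replicate 1 peak, 150 of 436 (34.4%) held it, against 426 of 3162 (13.5%) that did not, a difference of 20.9 points (95% interval 16.5 to 25.7; Fisher's exact test, two-sided, p = 2.4e-24). Of replicate 1 peaks, 143 of 431 shared (33.2%) and 6 of 52 single (11.5%) held it, a difference of 21.6 points (9.43 to 29.3; Fisher's exact p = 0.00124). GATA motifs were also more frequent in shared peaks, at 64.9% against 54.8% in replicate 2 and 64.3% against 38.5% in replicate 1. Shared replicate 2 peaks were also the stronger ones, so these shares overlap with those by peak strength.

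Immediate early genes had the highest share near MEF2A peaks of the 17 lists, in the conservative list at 5 kb; the lists were not tested against each other. Of 31 immediate early genes and activity-dependent MEF2 targets, 9 had a conservative summit within 5 kb of a TSS (29.0%, Wilson 95% interval 16.1 to 46.6), against 2.63% of the other protein-coding genes. They were Klf6 (signal value 139) and Nr4a1 (126), both with the MEF2 consensus in that promoter peak, Ier2 (101), the nuclear receptor genes Nr4a3 (90.7) and Nr4a2 (64.8, with a weaker promoter peak of 48.5 that held CTATAAATAA), the stress-response gene Atf3 (56.6), Egr2 (38.3), Jund (18.9) and Ier3 (15.4). The strongest peaks near Ier2, Nr4a3, Nr4a2, Atf3, Egr2, Jund and Ier3 lacked the consensus within 50 bp of the summit. The Klf6 peak lay at chromosome 13:5861156-5861351, 258 bp from the TSS, with CTAAAAATAG at 5861233-5861242. The Nr4a1 peak lay at chromosome 15:101254007-101254176, 190 bp from the TSS, with CTATTTTTAG at 101254074-101254083.

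Megakaryocyte genes came second, with 5 of 20 near a summit (25%, 11.2 to 46.9): Plek (67.5), Ppbp (63.9), which encodes a platelet chemokine, the integrin gene Itgb3 (34.8), the ETS factor gene Fli1 (31.6) and Gp5 (12.5), a platelet glycoprotein gene. Among these peaks, that of Ppbp alone held the MEF2 consensus, and that of Gp5 was in neither replicate's own list. Plek and Itgb3 lie on chromosome 11, which held 244 of the 1874 conservative peaks. The gene lists were not tested again without that chromosome. Of the erythroid membrane and globin list, 4 of 26 were near a summit (15.4%, 6.15 to 33.5): Tmod1 (209), Sptb (132), Add2 (34.9) and Epb41 (33.1), all of the membrane skeleton and none a globin gene. Of the MEF2 family and its partners, 4 of 26 were near one (15.4%, 6.15 to 33.5): Hdac5 (264), Mef2a itself (173), the arginine methyltransferase gene Carm1 (28.0) and the p38 kinase gene Mapk14 (23.5). Fisher's exact test, two-sided and adjusted over the 17 lists by Benjamini-Hochberg, gave p = 1.3e-06 for immediate early genes, 0.00125 for megakaryocyte genes and 0.0199 for each of the other 2 lists.

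The other 13 lists did not pass. They included erythroid transcription factors (2 of 24, Lyl1 and Ldb1, exact adjusted p = 0.378; 13 of 24 within 50 kb, 1.8e-05), heme and iron genes (1 of 24, Cpox, 0.902), muscle MEF2 targets (2 of 33, Smyd1 and Slc2a4, 0.533), ribosomal proteins (3 of 33, Rps9, Rpl27 and Rps3, 0.194), glycolysis (1 of 20, Pklr, 0.887) and the respiratory chain (1 of 28, Ndufs2, 0.902). No gene was near a summit in the lists of B and T lymphocytes, myeloid cells, hepatocytes and neurons (0 of 20 each, which allows up to 15% each), autophagy and lysosome (0 of 22, up to 13.6%), cell cycle (0 of 26, up to 11.5%) and histones (0 of 21, up to 14.3%). In the replicates' own lists, immediate early genes passed in both (5 of 31 in replicate 1, adjusted p = 3.8e-05; 9 of 31 in replicate 2, 1.6e-04; Fisher's exact test). The erythroid membrane list passed in replicate 1 alone (adjusted p = 0.00643 against 0.0587, exact), and the megakaryocyte (0.523 and 0.0761) and MEF2 family lists (0.0789 and 0.113) passed in neither. Within 50 kb of a TSS, erythroid transcription factors had the highest share of all lists (54.2%), and the MEF2 family list did not pass (6 of 26, exact adjusted p = 0.356). Within 1 kb, the megakaryocyte (exact adjusted p = 0.167) and erythroid membrane lists (0.203) did not pass, nor did the MEF2 family list in the 937 strongest peaks (0.141).

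**Figure D5:**
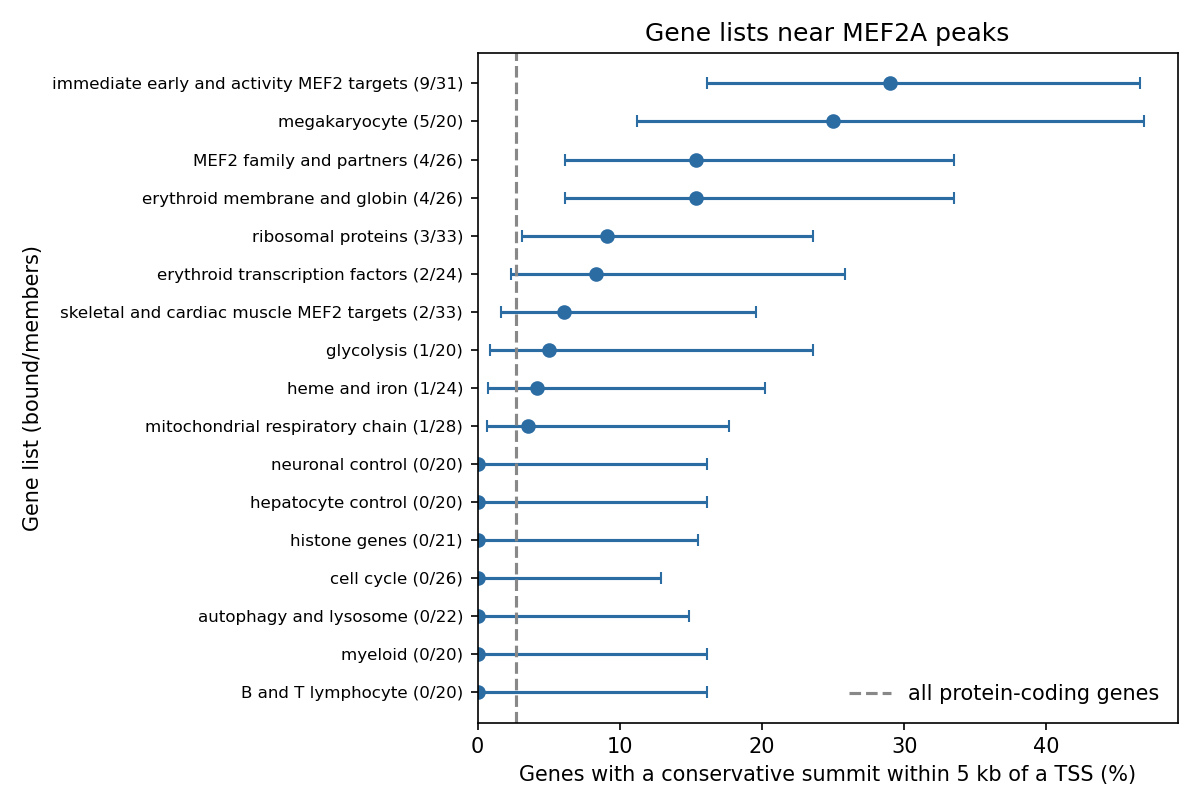
Share of each gene list (y, with bound and total members) that has a conservative summit within 5 kb of a TSS (x, percent, with Wilson 95% intervals), with all protein-coding genes as the dashed line at 2.67%. Immediate early genes stand at 29.0% and megakaryocyte genes at 25%.

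Among the MEF2 family, Mef2a was the only gene with a conservative summit within 5 kb of a TSS. The peak, at chromosome 7:67372747-67372971, lay 6 bp from the Mef2a TSS, held CTATTTTTAG at 67372851-67372860, and was in both replicates' own lists. For Mef2b, Mef2c and Mef2d the nearest conservative summits were 174988, 391563 and 195895 bp away, and Mef2d had a summit within 5 kb in the optimal list. None of Gata1, Tal1 and Klf1, which encode central erythroid regulators, and of the globin genes Hba-a1, Hbb-bs and Hbb-bt had a conservative summit within 5 kb. The nearest Gata1 TSS lay 19490 bp from the summit of a peak at the Hdac6 promoter. That peak, at chromosome X:7948390-7948476, held both motifs and had a signal value of 105. In the optimal list, Tal1 and Hbb-bt also had a summit within 5 kb.

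The optimal list, which came from the other processing run, reached further into weak sites than the conservative list. Of 5013 optimal peaks on assembled chromosomes, 1705 (34.0%, exact 95% interval 32.7 to 35.3) overlapped a conservative peak. Their median signal value was 36.7, against 17.7 for the 3308 that did not. The optimal list held the MEF2 consensus in 13.6% of its peaks and GATA motifs in 51.6%, and it had 1669 protein-coding genes within 5 kb of a summit, against 584 for the conservative list. Heme and iron genes (6 of 24) and erythroid transcription factors (6 of 24) passed the test in the optimal list (adjusted p = 0.0268 each, Fisher's exact test). Megakaryocyte genes (35%) had a higher share there than immediate early genes (32.3%).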

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

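The test of replicate 1's relaxed list, the strongest 100 peaks and the share of peaks with a near match were chosen after the results were seen. The other tests were written down before their values were computed. Those for chromosome 11 were then taken out, its densities were computed, and they were put back unchanged. The design has 1 group, so no biological difference between groups was tested.

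Replicate 1's relaxed list held 26 entries on the mitochondrial chromosome, which the comparisons did not use, with signal values up to 74.4. Replicate 2's relaxed list held 0. From the other processing run, replicate 1's ranked list held 21 and its thresholded list 0.

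Replicate 1 passed 483 peaks and replicate 2 passed 3598. Of the 3162 replicate 2 peaks missing from replicate 1's thresholded list, 63.7% had an entry in its relaxed list from the other processing run. That was 24.9 times the 2.56% of randomly placed peaks. Weaker enrichment or lower depth in replicate 1 at the same sites is thus a candidate explanation. The random placement was uniform along each chromosome and not matched for kind of sequence, so the ratio does not show MEF2A binding there. Of all 3598 replicate 2 peaks, 1150 had no entry in replicate 1's relaxed list. A difference in the kind of site was also tested: within 10 strata of replicate 2 signal, peaks also called in replicate 1 held the MEF2 consensus more often, with a stratified odds ratio of 1.45 (95% interval 1.09 to 1.94) against 3.37 without strata. Most of the difference in motif share thus went with peak strength, and a part may go with the kind of site. Of the 436 shared peaks, 250 lay in the strongest stratum and 104 in the next, and signal still varied within strata. The remaining odds ratio may therefore also come from strength, and the test cannot separate the 2. Depth and enrichment cannot be separated without read counts.

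Most conservative peaks lacked the MEF2 consensus: 902 of 1874 held a GATA motif without it and 572 held neither. Dilution by weak peaks is argued against as the whole cause, since 34% of the strongest 100 held the consensus (Wilson 95% interval 25.5 to 43.7). Weak peaks did lower the share, which was 38.4% in the strongest of the 4 classes by signal value and 7.91% in the weakest. Too strict a consensus may account for a part: near matches with 1 mismatch were 1.59 times as frequent at summits as in flanks (bootstrap 95% interval 1.39 to 1.84, which includes the 1.5 set as the bound). However, 34.9% of the peaks without the consensus held one. Where the flank also lacked the consensus (1447 peaks), 35.0% of summit windows and 19.1% of flank windows held a near match. A part of the 34.9% is thus background. Near matches do not cover the whole of the peaks without the consensus. Recruitment beside or through GATA factors stays open: GATA motifs at these peaks were 3.46 times as frequent as in their flanks, but their share (61.2%) exceeded that of peaks with the consensus (57%) by 4.19 points (−1.19 to 9.67), which is within error. Neither test shows how MEF2A reaches a site.

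Chromosome 11 held 244 of the 1874 conservative peaks, 2.05 per assembled Mb against a median of 0.619 over the other autosomes. Gene density is argued against as the whole cause, since peaks per annotated TSS were 2.40 times those of the other autosomes together (Poisson 95% interval 2.11 to 2.72). A gain of chromosome 11 DNA that the control does not remove is a candidate explanation: relaxed-list entries over 50 kb from any TSS were 1.73 times as dense there as on the median autosome in replicate 1 and 1.63 times in replicate 2. Chromosome 15 had like ratios of 1.71 and 1.91. It held 126 conservative peaks on its 101 Mb, against 244 on the 119 Mb of chromosome 11. Per 1000 TSSs the rates were closer, at 48.1 (Poisson 95% interval 40.0 to 57.2) and 56.2 (49.4 to 63.8), with overlapping intervals. The autosomes other than 11 held 23.5 together. A gain is thus not shown to account for the whole excess, nor shown to fall short of it. Replicate 2's relaxed list also stops at 300000 entries. Relaxed-list entries over 50 kb from TSSs were also dense on chromosomes 9, 17 and 19. Replicate 1 had 40.9, 39.3 and 35.4 per Mb there, against 29.3 on the median autosome. Replicate 2 had 119, 105 and 102, against 80.8. Chromosomes 9 and 17 held 28.0 and 20.5 conservative peaks per 1000 TSSs, and 19 held 39.7. Per Mb, chromosomes 9, 17 and 19 held 0.966, 0.796 and 1.48 conservative peaks, against the median of 0.619. Denser entries there thus went with more peaks per Mb. Per 1000 TSSs, the Poisson 95% intervals of chromosomes 9 (23.2 to 33.6) and 17 (16.1 to 25.8) included the 23.5 of the autosomes other than 11. Copy number itself was not measured, and regulatory density away from TSSs was not tested.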

How the results depend on the processing

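Alternatives concerning overlapping peaks and chromosome 11 were chosen after seeing the data; the others were set before. Of the alternatives to main values, 87 kept direction and side of the threshold or, for values and counts with no test, stayed close; 14 moved in size, 5 newly passed the threshold, 1 fell short of it and 2 turned direction. For single motifs and gene lists, 248 stayed on their side of the threshold, some with the sign turned where neither value passed, 37 fell short of the threshold and 12 newly passed it; NF-Y turned sign past the threshold, to −1.29 points against GC-matched windows and −1.81 against shuffled ones. The share of replicate 1 peaks found in replicate 2 was 78.7% with 50% reciprocal overlap, 98.3% in the stronger part of each list and 62.1% with equal list lengths; the reverse share was 10.6%, 13.3% and 61.9%. The correlation of replicate signals was 0.430 in the optimal list and 0.676 as Pearson's r of log2 values. The intron excess was 1.29 points with promoters up to 5 kb. Motifs above the flank numbered 7 in the stronger 937 peaks, 9 within 25 bp of the summit and 7 to 14 with 1 replicate left out. They numbered 15 without the weaker of 40 overlapping pairs and 15 without chromosome 11. The distal minus promoter difference in the MEF2 consensus was 7.95 points in the optimal list, 6.22 within 100 bp and 0.811 within 25 bp of the summit, 6.98 and 4.14 with promoters up to 500 bp and 5 kb, −9.65 in the stronger 937 peaks, and −11.3 (replicate 1's list, without replicate 2) to 8.34 (without replicate 1). Gene lists past the threshold numbered 2 at 1 kb from a TSS and 1 to 2 with 1 replicate left out, against 4. The cause was not tested, except for the turn in the stronger 937 peaks, whose tests were set aside without weighing. No paired analysis was possible because the series has 1 group. Depth is unknown, so a site missing from a list was not shown to be unbound.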

Other observations

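The tests in this part were all chosen after the data were seen. Some strong promoter peaks with the MEF2 consensus belonged to genes outside the fixed lists. In all, 42 protein-coding genes had a conservative summit with the consensus within 1 kb of a TSS as their strongest peak there. They included Ankrd40 (signal value 130), Lrrc39 (126), Sil1 (119), Klhdc1 (111), the deacetylase gene Hdac6 (105), the phosphatase gene Dusp16 (86.9), the circadian gene Per1 (84.3), Tsc22d1 (80.1) and Klf7 (75.9). The Per1 peak lay 40 bp from its TSS at chromosome 11:69099970-69100265 with CTAAATATAG at 69100137-69100146. The Hdac6 peak held CTAATAATAG at 7948446-7948455 on chromosome X, beside a GATA motif.

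Several genes held 3 or more summits, which was not compared with chance for genes of their length. The most, 9, lay in Gm20388, a locus of 4435 kb. Prkca, which encodes protein kinase C alpha, had 5 conservative summits within its 411 kb, all 5 with a GATA motif and 0 with the MEF2 consensus. Meis1, a homeobox gene of blood progenitors, had 4, of which 4 held a GATA motif and 1 the MEF2 consensus. Kat6b had 4 with the same counts, and Erg, an ETS factor gene, had 3, with signal values up to 200. Prkca and Meis1 lie on chromosome 11, which held an excess of peaks for its length.

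At summits, CTAAAAATAG and its reverse complement made up 88 of 408 matches to the MEF2 consensus, against 3 of 78 matches in both flanks. CTAAAAATAA had 43 against 3, CTATTTTTAA 42 against 5 and CTATAAATAG 41 against 0, whereas TTAAAAATAA had 15 against 9. The median distance from summit to the nearest match was 16.5 bp for the MEF2 consensus and 16.5 bp for the GATA motif.

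The turn in direction between promoter and distal peaks was described further by a logistic model of the MEF2 consensus on promoter position and log2 signal. Explanations by GC content, by the mix of weak promoter peaks, and by a lack of the motif beyond the flanks of those peaks were tested and then set aside, so the values stand without weighing. The promoter by signal term was 0.82 (95% interval 0.44 to 1.21) in log odds per doubling of signal, and 0.72 (0.34 to 1.1) with the GC content of the window in the model. Promoter peaks made up 12.8% of the stronger 937 peaks and 24.9% of the weaker. The weaker promoter peaks had a median GC content of 62.4%, against 48.0% for the stronger ones, and held the consensus more often than their flanks did (6.44% against 1.29%, exact McNemar p = 0.00754).

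Of the 1874 conservative peaks, 23 had no overlapping entry in at least 1 of the replicates' relaxed lists. One of them was the peak near Slc38a2, which ranked 9 by signal value and was in both replicates' thresholded lists, made in the other processing run.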
